A study of Mus musculus with 6 samples.

How the data were processed

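Total RNA from 6 samples of MIN6B1 cells, 3 transfected with siGFP and 3 with circHIPK3 siRNA for 48 h, was labelled with a single dye and hybridised to Agilent mouse expression arrays, per the labels' protocols. The deposited scanner files give a background-subtracted intensity for every spot on a linear scale, made with Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. They also hold raw foreground and background intensity medians and flags for spots that are well above background, saturated or not uniform. A deposited value table holds log2 values of the same arrays. Its column medians lie between 9.7965 and 9.7968, and its columns correlate at 0.9999 or above with the log2 processed intensity of the same array, so that the direction is as measured and genes were not centred. The normalization and the probe filter the authors used for the log2 table are not given in the sources used here. Its 31868 probes served as an alternative.

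The main values were log2 processed intensities minus each array's 75th percentile over the 43020 non-control spots. Spots flagged as not uniform or as population outliers were left out and spots of a probe were averaged, which left 12 of 39429 probes without a value on an array. A probe was kept when well above background on all 3 arrays of at least 1 group, which held for 31371 probes. No probe was saturated on any array. The 75th percentiles were 2939, 3669 and 3386 units for the siGFP arrays and 3590, 3668 and 3421 for the circHIPK3 siRNA arrays. Probes were named by matching the accession in the files to a RefSeq table of assembly GRCm38.p6, which gave a symbol to 27228 probes and none to 12201, which kept the file's name. The files name another genome build, so no coordinates are printed. The probe with the highest mean signal stood for each gene. That left 25772 genes and unnamed transcripts, of which 17156 had a symbol and 4431 of these had several kept probes. No other column of sample values was present in the value table.

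Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Single values of 3 against 3 arrays were also given an exact permutation test. The 23 gene lists, with 754 symbols of which 699 were measured, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. By fry's test of movement in a single direction 2 lists passed, the genes the study followed and cytoskeleton and adhesion (adjusted p = 0.00908 for both). That test does not set a list against other genes: the median of all genes was 0.08, and the cytoskeleton list had a median of -0.0015 relative to it, with 24 of 48 members below it. List medians were also set against 10000 random lists matched on mean signal in 40 bins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The named genes follow a rule written before the data were examined, as do the groups, the tests, the lists and most alternatives: the 12 highest and 12 lowest changes among called genes with a symbol and non-overlapping groups, Hipk3, Akt1, Mtpn and Slc2a2, and per list up to 4 called members or up to 2 uncalled members with the smallest p.

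The procedure was tested on simulated data for the comparison of circHIPK3 siRNA with siGFP, over 25772 genes and 20 runs with 200 changed genes each. It recovered 19.5% of the genes changed 1.5-fold, 62.5% of those changed 2-fold and 83.4% of those changed 3-fold, and 3.85% of its calls were false. A simulated shift of 0.3 in the list of 47 beta cell genes was called in 20 of 20 runs. That shift was larger than the median change of -0.18 relative to all genes found for this list. The simulated noise was independent between genes and arrays, with no slide difference and no trend with brightness. These rates therefore need not hold for the measured arrays.

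Each alternative replaced a single step, of which the value table changes both normalization and probe filter, and trend and robust variance are set together: quantile normalization, median scaling, the value table, no filter or a stricter filter on dim probes, all probes of a gene, trend and robust variance, array weights, the replicate number as a block, the slide as a block, and each array left out. Normexp with an offset of 50 on the median foreground, cyclic loess, slide as a random block and the first slide alone were added after seeing the data, the first because the mean foreground that the plan named is not a column of the files used here. The planned test of microRNA sites in 3' untranslated regions was not run, since no transcript sequences were used here. Probe and siRNA sequences were not used either, so a match of the siRNA to other transcripts was not analysed here.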

Results

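The arrays measured RNA in MIN6B1 cells, a mouse insulinoma line that retains insulin secretion and is used as a model of the pancreatic beta cell. The cells were transfected with a small interfering RNA (siRNA) against circHIPK3, a circular RNA made from the Hipk3 gene, or with an siRNA against green fluorescent protein (siGFP) as the control. Total RNA was collected 48 h later. Each group held 3 samples, and each sample was hybridised to its own single-colour Agilent array. The labels do not state that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The 75th percentile of the processed signal lay between 2939 and 3669 units per array, and between 77.7% and 83.5% of probes were well above background. The 3 siGFP arrays and circHIPK3 siRNA replicate 1 shared a slide, and circHIPK3 siRNA replicates 2 and 3 lay on another. Leaving out circHIPK3 siRNA replicate 1 therefore puts the groups on separate slides. A call gained in that setting cannot be told from a difference between slides. With 6 arrays, their number limits the precision. Changes are given on the log2 scale as circHIPK3 siRNA minus siGFP, with the standard error (SE) of the limma fit, and adjusted p-values are two-sided limma values with Benjamini-Hochberg adjustment over 25772 genes and unnamed transcripts.

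The siRNA was directed at the circular RNA, and Hipk3, which encodes a homeodomain-interacting protein kinase, was examined first. The brighter of the 2 Hipk3 probes gave a log2 signal of 2.81 ± 0.14 (SD, n = 3) in the siGFP arrays and 2.64 ± 0.21 (SD, n = 3) in the circHIPK3 siRNA arrays. The change was -0.17 ± 0.14 (SE) with an adjusted p of 0.50, and the ranges of the groups overlapped. The second probe gave -0.31 ± 0.12 (SE). Two-sided exact permutation tests of the single-array values gave p = 0.30 and p = 0.20, where the smallest p that 3 against 3 arrays allow is 0.10. The place of these probes relative to the circularised exon is not known here, so their values check neither the level of the circular RNA nor the sample labels. No other member of the Hipk family passed the test among the 4 measured, with Hipk2 at -0.30 ± 0.15 (SE, adjusted p = 0.284) by its brighter probe and -0.02 ± 0.12 (SE) by its second.

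**Figure D1:**
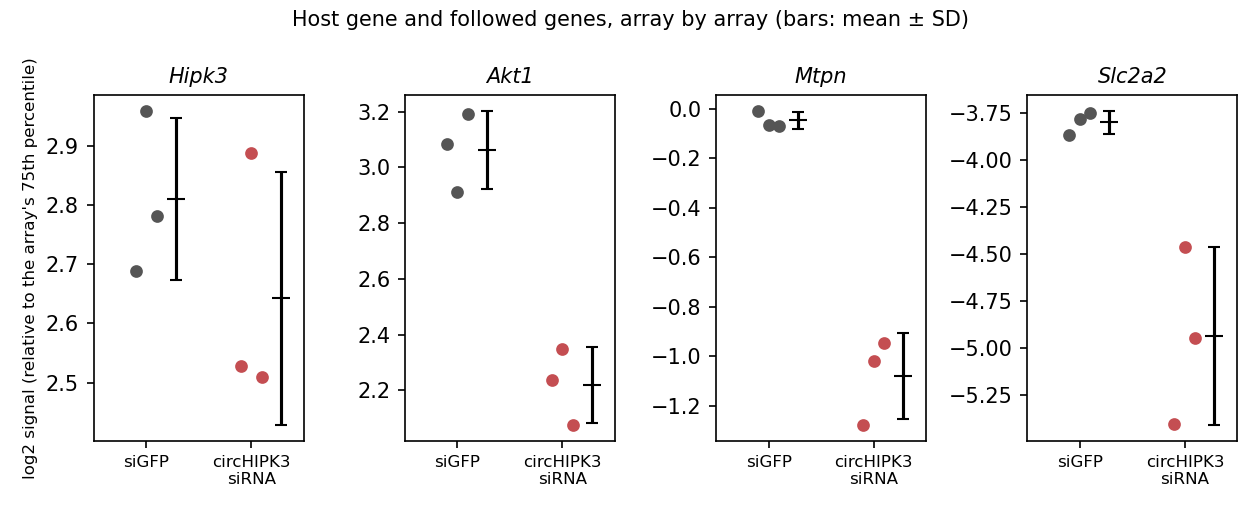
Log2 signal relative to the array's 75th percentile (vertical axis, a separate range per panel) of Hipk3, Akt1, Mtpn and Slc2a2 on each siGFP array (grey, n = 3) and each circHIPK3 siRNA array (red, n = 3), with the group mean ± SD as bars. The groups overlap for Hipk3 and do not overlap for Akt1, Mtpn and Slc2a2.

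The study followed Akt1, Mtpn and Slc2a2 in relation to microRNAs that circHIPK3 was proposed to hold. Akt1 encodes a kinase of the insulin signalling cascade, Mtpn encodes myotrophin, and Slc2a2 encodes the glucose transporter GLUT2. Mtpn fell from a log2 signal of -0.05 ± 0.03 (SD, n = 3) to -1.08 ± 0.17 (SD, n = 3), a change of -1.04 ± 0.11 (SE) and 2.05-fold, with an adjusted p of 0.0285. Akt1 fell from 3.06 ± 0.14 (SD, n = 3) to 2.22 ± 0.14 (SD, n = 3), a change of -0.84 ± 0.12 (SE) and 1.79-fold, with an adjusted p of 0.0379. Slc2a2 lay at -3.80 ± 0.06 (SD, n = 3) and -4.93 ± 0.47 (SD, n = 3), a change of -1.14 ± 0.22 (SE) that missed the threshold at an adjusted p of 0.0584. Each gene had 1 probe, and all 3 circHIPK3 siRNA arrays lay below all 3 siGFP arrays for each of them, which gave the smallest exact permutation p of 0.10. With slide as a block, a fit that rests on circHIPK3 siRNA replicate 1 against the siGFP arrays of its own slide, the changes were -0.82 ± 0.18 for Akt1, -1.23 ± 0.13 for Mtpn and -1.60 ± 0.20 for Slc2a2 (SE), and none passed (adjusted p = 0.191, 0.0932 and 0.108, within ranges over all alternatives of 0.00321 to 0.200, 0.00238 to 0.149 and 0.0278 to 0.204). The calls of Akt1 and Mtpn were lost on leaving out any siGFP array or circHIPK3 siRNA replicate 2 or 3. The limma adjusted p then lay from 0.0782 to 0.161 for Akt1 and from 0.0705 to 0.149 for Mtpn. Slc2a2 passed without circHIPK3 siRNA replicate 1 (limma adjusted p = 0.0338). Directions were kept throughout, which non-overlapping groups fix in advance when an array is left out. Because the study chose these genes, their shared direction is not independent evidence.

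Across all genes, 303 passed the threshold, of which 165 were lower and 138 were higher after circHIPK3 siRNA. Under the 75th percentile scaling, falls and rises lay at different signal levels. Among the 12886 genes at or above the median signal, 129 fell and 18 rose, whereas among the 12886 below it, 36 fell and 120 rose. The groups did not overlap for 6685 genes, 25.9% of those tested, where chance gives 10%, and of these 4267 were higher and 2418 lower, the opposite balance to that of the called genes. The 10% holds only if any array could equally have been in either group, and slides were partly divided by group. In this scaling the median change was 0.08 for all genes and 0.28 for the 6443 dimmest, which bears on that balance. The split between directions moved with the scaling: quantile normalization gave 218 lower and 44 higher, with 128 falls and 14 rises at or above the median signal and 90 falls and 30 rises below it, so that falls were the more numerous on both sides. In both settings 195 genes were called. Without circHIPK3 siRNA replicate 1, which leaves the groups on separate slides, 1736 genes were called, 1385 higher and 351 lower. The count was 0 without siGFP replicate 1, 2 or 3 or circHIPK3 siRNA replicate 3, and 1 without circHIPK3 siRNA replicate 2. It was also 0 with slide as a fixed block by limma (2675 genes at an unadjusted p under 0.05, against 5445 without the block) and 125 with slide as a random block.

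**Figure D2:**
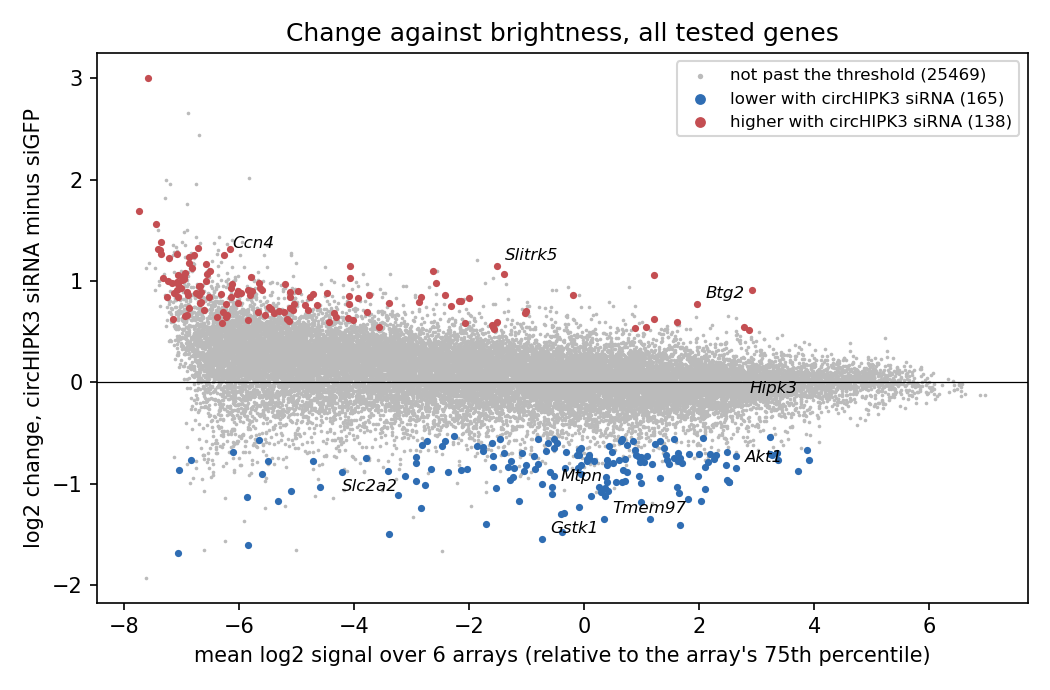
Log2 change, circHIPK3 siRNA minus siGFP (vertical axis), against the mean log2 signal over the 6 arrays relative to the array's 75th percentile (horizontal axis), with 1 point per tested gene. Of the 165 genes called lower (blue) 129 lie at or above the median signal, and of the 138 called higher (red) 120 lie below it, a split that did not hold for the dimmer genes under quantile normalization.

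The 12 called genes with the lowest changes were of several kinds. Gstk1, a glutathione S-transferase of mitochondria and peroxisomes, fell by 1.55 ± 0.14 (SE) on the log2 scale, which was 2.92-fold (adjusted p = 0.0275). Derl3, a component of endoplasmic reticulum-associated degradation, fell by 1.47 ± 0.23 (SE), Trappc2l, a subunit of a vesicle tethering complex, fell by 1.35 ± 0.14 (SE), and Tmem97, a membrane protein linked to cholesterol handling, fell by 1.35 ± 0.11 (SE). Smaller falls were those of the mitochondrial adenylate kinase Ak3 at -1.28 ± 0.14 (SE), the O-fucosyltransferase Pofut2 at -1.23 ± 0.16 (SE) and the collagen-modifying lysyl hydroxylase Plod3 at -1.18 ± 0.12 (SE). Ces1d, a carboxylesterase gene, had a fitted change of -1.60 ± 0.21 (SE), but it was well above background on 2 of the 3 circHIPK3 siRNA arrays and its change was -0.77 with normexp, so that the size of its fall is not well determined. The lens crystallin gene Crybb1 fell by 1.49 ± 0.13 (SE) and its second probe gave -1.61 ± 0.14 (SE). The interferon-induced gene Rsad2 (-1.40 ± 0.23, SE), the decoy receptor gene Tnfrsf23 (-1.30 ± 0.16, SE, and -0.76 ± 0.14, SE, by its second probe) and the histone gene H3c1 (-1.17 ± 0.17, SE, and -0.74 with normexp) complete the 12. Their adjusted p-values lay between 0.0271 and 0.0489. Under quantile normalization Rsad2 lost its call at a change of -1.47 and the other 11 kept theirs. With slide as a block all 12 remained lower, by 1.00 to 1.59, and none passed. That fit sets circHIPK3 siRNA replicate 1 against the siGFP arrays. Since the genes were chosen for non-overlapping groups, its direction was fixed in advance and only the size is informative.

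Of the 12 highest called genes, 9 were not well above background on any siGFP array, so that only a lower bound on the fold, under the 75th percentile scaling, can be given. These were the olfactory receptor genes Olfr1504 (at least 1.21-fold), Olfr167 (at least 2.41-fold) and Olfr688 (at least 1.60-fold), the vomeronasal receptor gene Vmn1r77 (at least 1.16-fold), Klhl6 (at least 1.16-fold), Ccn4, which encodes a matricellular protein (at least 2.36-fold), Faiml (at least 1.25-fold), Syndig1 (at least 1.91-fold) and the anion transporter gene Slc26a7 (at least 1.45-fold). Each bound sets the mean of the circHIPK3 siRNA arrays against the lowest signal counted as well above background on the siGFP arrays, or the probe's own signal where that is higher. These bounds hold for that scaling alone. With normexp the log2 changes of the 9 genes were 0.13 to 0.39, below the bound of each except Klhl6, and under quantile normalization those of Ccn4, Olfr167 and Syndig1, at 0.99, 1.05 and 0.88, were also below it. The other 3 were measured in both groups. Slitrk5, a neuronal membrane protein gene, rose by 1.14 ± 0.12 (SE), which was 2.21-fold. Gbp7, an interferon-inducible guanylate-binding protein gene, rose by 1.15 ± 0.18 (SE), and Slc4a11, a membrane transporter gene, rose 2.14-fold (SE of the log2 change 0.14). The adjusted p-values of the 12 lay between 0.0271 and 0.0436. Under quantile normalization Gbp7, Faiml, Klhl6 and Olfr1504 lost their calls. All 12 remained higher in the slide-blocked fit and none passed. Here too the choice of genes with non-overlapping groups fixed the direction in advance.

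Among 47 measured genes of beta cell identity and glucose sensing, none rose or fell at the threshold over all genes. Adjusted over the list alone, 3 passed, all lower. These were Slc2a2, Nnat (-0.55 ± 0.11, SE, adjusted p = 0.0618 over all genes) and the taste-pathway cation channel gene Trpm5 (-0.59 ± 0.12, SE, adjusted p = 0.0630 over all genes), which was chosen after its value was seen. Nnat passed under 5 processing alternatives and without circHIPK3 siRNA replicate 1. Its second probe gave -0.69 ± 0.11 (SE, limma adjusted p = 0.0417 over all kept probes). The insulin genes Ins1 and Ins2 gave -0.12 ± 0.09 and -0.12 ± 0.10 (SE) and the transcription factor genes Pdx1 and Mafa gave 0.04 ± 0.12 and -0.02 ± 0.12 (SE), all 4 likewise named afterwards and none past the threshold. The median change of all genes was 0.08, and dividing by the array median in place of the 75th percentile shifted it by -0.10, so list changes are given relative to the median of all genes. On that basis the beta cell list had a median of -0.18, which was -0.09 under quantile normalization, and 40 of its 47 members lay below the median of all genes. Before that subtraction the list median was -0.10, where signal-matched random lists had 0.01. Part of the distance from the median of all genes therefore goes with signal level. On the same scale, the list had array medians of -0.11, -0.12 and -0.09 for circHIPK3 siRNA and -0.04, -0.00052 and 0.03 for siGFP. It passed limma's camera test with the preset correlation of 0.01 (adjusted p = 3.6e-05) but not with an estimated correlation (adjusted p = 0.181 with an estimated correlation). In the insulin exocytosis machinery, 1 of 40 members fell, Mtpn, and 39 did not pass. Adjusted over the list alone, 4 were lower and 1 was higher, and the median was -0.13 (camera adjusted p = 0.00318, and adjusted p = 0.406 with an estimated correlation), and with slide as a block the median was -0.04 and the camera call was lost. Before subtraction of the all-gene median, circHIPK3 siRNA replicate 1 (-0.00056) lay within the siGFP range of -0.06 to 0.04 for this list. The housekeeping list had a median of -0.11 on the same scale as the list medians. Among the 36 insulin and AKT signalling genes 1 fell, Akt1, 3 were lower when adjusted over the list alone, and the list did not pass (median -0.04, adjusted p = 0.170).

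Histone genes had the lowest list median after the 3 genes the study followed. Of 31 measured, 1 passed over all genes, H3c1. Adjusted over the list alone 18 passed, all lower, and 26 lay below the median of all genes. The list median was -0.45 relative to all genes and -0.37 before that subtraction. The array medians, before subtraction, were -0.29, -0.36 and -0.46 for circHIPK3 siRNA against 0.14, -0.12 and -0.01 for siGFP. The camera adjusted p was 1.5e-12, and adjusted p = 0.406 with an estimated correlation. The slide-blocked median was -0.33. In the cell cycle and proliferation list 1 of 59 genes fell, the mitotic cyclin gene Ccnb1 (-0.75 ± 0.13, SE, adjusted p = 0.0489, a call lost under quantile normalization at -0.72), and 2 were lower when adjusted over the list alone. Its median was -0.16 (-0.10 under quantile normalization), with 54 of 59 members below the median of all genes (camera adjusted p = 5.9e-06, and adjusted p = 0.485 with an estimated correlation). Before subtraction of the all-gene median, the list median was -0.07, where signal-matched random lists had -0.0021. Part of the distance from the median of all genes goes with signal level here as well. On the same scale, the array medians were -0.13, -0.0095 and -0.13 for circHIPK3 siRNA replicates 1 to 3. Those for siGFP were -0.06, 0.02 and 0.03, so that circHIPK3 siRNA replicate 2 lay within the siGFP range. In the list of p53 targets and apoptosis genes, Cdkn1a, which encodes a cyclin-dependent kinase inhibitor, fell by 0.81 ± 0.11 (SE) and Ccng1 fell by 0.62 ± 0.11 (SE), while the antiproliferative gene Btg2 rose by 0.77 ± 0.13 (SE). The other 34 did not pass, 2 were higher and 2 lower when adjusted over the list alone, and the list as a set did not (median -0.08, and 0.01 with slide as a block, adjusted p = 0.170).

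The 3 genes the study followed also passed as a list (median -1.12, camera adjusted p = 7.0e-06, adjusted p = 0.181 with an estimated correlation, 3 lower when adjusted over the list alone). Literature targets of miR-124-3p, which include Mtpn, had a median of -0.10, with 1 of 48 lower and 1 when adjusted over the list alone (camera adjusted p = 0.00307, and adjusted p = 0.278 with an estimated correlation). That call was lost under quantile normalization, where the median was -0.04, and with slide as a block. Literature targets of miR-338-3p had a median of -0.01, none of 15 passed over all genes or adjusted over the list alone, and Met and Zeb2 lay at 0.42 ± 0.20 and 0.42 ± 0.16 (SE), with a second Zeb2 probe at 0.95 ± 0.19 (SE). Toward lower values 4 further lists passed the preset test, and all 4 lost it under quantile normalization, with slide as a block and without circHIPK3 siRNA replicate 2. They were the unfolded protein response (44 genes, median -0.12, Edem1 at -0.61 ± 0.13, SE), cholesterol and fatty acid synthesis (35 genes, Fads2 at -0.63 ± 0.12 and Elovl6 at -0.78 ± 0.16, SE), mitochondrial respiration (53 genes, median -0.11, in which the respiratory complex gene Ndufs3 fell by 0.70 ± 0.11, SE) and housekeeping genes (25 genes, median -0.11, Hprt at -0.38 ± 0.10, SE). Under quantile normalization the medians of these 4 lists were -0.07, 0.04, -0.03 and -0.05, and with slide as a block -0.04, -0.01, -0.04 and -0.02. Edem1, Fads2 and Elovl6 missed the threshold here and passed with normexp, median scaling, trend and robust variance, and array weights, and Fads2 and Elovl6 also without circHIPK3 siRNA replicate 1. The adjusted p-values of the 4 lists were 0.0227, 0.0389, 0.0219 and 0.0252, and with an estimated correlation the adjusted p-values were 0.449, 0.614, 0.540 and 0.489. Adjusted over each list alone, 0, 4, 1 and 0 genes were lower and 0 higher. Among 10000 signal-matched random lists their medians lay at percentiles 5.67, 92.5, 21.3 and 10.3, so that the cholesterol list lay toward the high end. The beta cell, histone, cell cycle, exocytosis and interferon lists lay at percentiles 0, 0, 0.29, 1.38 and 0.54. Immediate early genes lay at 98.9 and stromal, endothelial and immune genes at 98.6. The random lists were drawn without regard to correlation between members, so these percentiles are not p-values. The cholesterol call was also lost without siGFP replicate 1, the mitochondrial call without siGFP replicate 3, the unfolded protein call without circHIPK3 siRNA replicate 3 and the housekeeping call without either of the last 2 arrays. The cholesterol list had a median of -0.03 relative to all genes and 0.04 under quantile normalization, and its median before subtraction was 0.05 while its mean was -0.05. In all, 10 of the 23 lists passed with the preset correlation, 0 with an estimated correlation, 5 under quantile normalization, 4 with slide as a block and 6 without circHIPK3 siRNA replicate 2. The estimated correlation was 0.44 for the histone list. It was 0.0163 for the beta cell list and 0.0165 for miR-124-3p targets, near the preset 0.01. For those lists a high correlation between members therefore does not account for the lost call. In the p53 list the estimated correlation, 0.0077, was below the preset, yet the unadjusted camera p rose from 0.104 to 0.169. The estimated form of the test thus gives larger p-values for reasons other than correlation as well. Its 0 calls do not by themselves show correlated members.

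Type I interferon response genes went both ways. Herc6 rose by 0.76 ± 0.12 (SE) and Rsad2 fell, 36 of 38 did not pass, and adjusted over the list alone 4 were higher and 3 lower (camera adjusted p = 0.144). The median was -0.10, it was 0.06 with slide as a block, and the list passed without circHIPK3 siRNA replicate 1. Under quantile normalization neither Herc6 nor Rsad2 passed. No gene of the remaining 8 lists passed over all genes, and adjusted over the list alone 1 glycolysis gene and 1 delta or PP cell gene were lower and no other passed. Among markers of other cell types the medians were 0.19 for exocrine and duct genes (17 measured), 0.17 for stromal, endothelial and immune genes (16 measured), 0.03 for delta and PP cell genes (9 measured) and -0.11 for alpha cell genes (12 measured), with camera adjusted p-values from 0.170 to 0.792. Under quantile normalization the exocrine and duct median was 0.08, and with slide as a block the stromal, endothelial and immune median was 0.02. Before subtraction of the all-gene median, the exocrine and duct medians were 0.15, 0.19 and 0.32 on the circHIPK3 siRNA arrays against 0.12, -0.15 and -0.01 on the siGFP arrays. Spp1 lay at 0.47 ± 0.15 and Muc1 at 0.51 ± 0.13 (SE), the latter 0.31 with normexp. Also before subtraction, the stromal, endothelial and immune medians were 0.06, 0.23 and 0.48 against 0.16, -0.09 and -0.04. The collagen gene Col3a1 lay at 0.52 ± 0.15 (SE), which was 0.27 under quantile normalization and 0.14 with normexp. In the alpha cell list Fev lay at 0.49 ± 0.14 (SE) and at 0.24 with slide as a block, and passed without circHIPK3 siRNA replicate 1 at 0.61, and in the delta and PP cell list the ghrelin receptor gene Ghsr lay at -0.69 ± 0.15 (SE, adjusted p = 0.0747), passed under quantile normalization at -0.94 and ranged from -0.98 to -0.31 over the alternatives. The delta and PP cell list turned to -0.05 under quantile normalization. The medians of genes normally low in beta cells (26 measured), of immediate early genes (32 measured), of glycolysis genes (22 measured) and of cytoskeleton and adhesion genes (48 measured) were 0.12, 0.07, -0.02 and -0.0015, and no camera test passed for these lists, except for glycolysis without siGFP replicate 1. The camera test pointed lower for delta and PP cell genes and higher for cytoskeleton and adhesion genes, opposite in sign to their medians. The phosphofructokinase gene Pfkl lay at -1.08 ± 0.23 (SE, adjusted p = 0.0668) and passed with normexp and median scaling. The last 2 turned sign to 0.04 and 0.03 under quantile normalization.

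**Figure D3:**
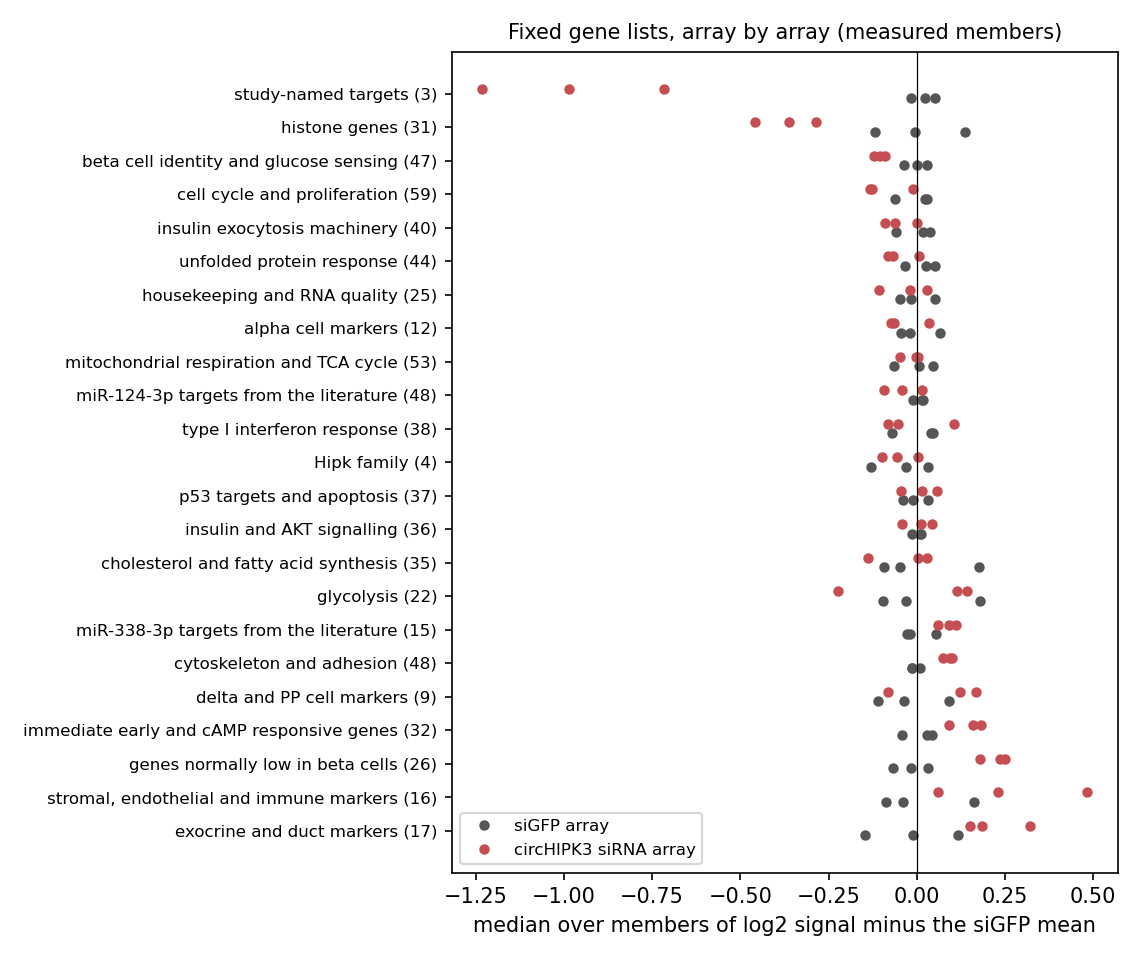
Median over the measured members (number in brackets) of each fixed gene list of the log2 signal minus the siGFP mean (horizontal axis), for each siGFP array (grey, n = 3) and each circHIPK3 siRNA array (red, n = 3). In this scaling the circHIPK3 siRNA arrays lie below all siGFP arrays for the 3 genes the study followed, between -1.23 and -0.72, the histone genes, between -0.46 and -0.29, and the beta cell genes, between -0.12 and -0.09, and above them for 5 lists (miR-338-3p targets, genes normally low in beta cells, exocrine and duct, immediate early, and cytoskeleton and adhesion genes). The values are before subtraction of the all-gene median of 0.08. Relative to it, miR-338-3p targets and cytoskeleton and adhesion genes had medians of -0.0059 and -0.0015.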

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

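The tests of slide, scaling, control probes, second probes and DNA replication genes, and the count of called genes over other divisions of the arrays, were chosen after the results they bear on were seen. Of the 10 ways to divide the 6 arrays into groups of 3, with a division and its mirror image taken as the same, 1 gave as many called genes: the real one called 303 and the highest of the others called 0 by limma, with 180 to 3257 genes at an unadjusted p under 0.05 against 5445. For gene lists, 2 of the 10 divisions gave as many calls as the real one: the real division called 10 lists and another, which set siGFP replicate 1 with both arrays of the second slide, called 12. With slide as a fixed block 4 lists passed. With 10 divisions no share under 0.05 can be reached.

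The first pattern is the rise of 120 genes below the median signal. Rises depended on the probe filter more than falls did. With probes well above background on all 6 arrays, 78 genes were called higher over all signal levels against 138 at first, and 161 lower against 165. Under quantile normalization, which removes a trend with brightness, 28 of them kept their call while 90 genes in that range were called lower, and their median change went from 0.87 to 0.65 with a median SE of 0.13 in both, so the calls ended with a smaller change rather than with a wider spread. Of the 1180 such genes called higher without the circHIPK3 siRNA array of the first slide, 976 also lay higher on that array. It showed a median of 0.23 against 0.74 for the arrays of the second slide, which with the siGFP arrays had served to choose the genes. All genes below the median signal had medians of 0.09 on that array and 0.27 on the second slide. Viral and synthetic control probes without a mouse transcript (10 of 22 kept by the same filter) moved by a median of 0.30, against 0.28 for the 6443 dimmest genes. Of the kept probes 9 were higher, though siGFP replicate 1 at 0.18 lay above circHIPK3 siRNA replicate 1 at 0.14. The control probes left out by the filter went both ways, from -0.27 to 0.61. A trend with brightness, the second slide and signal not tied to a transcript may each contribute, and an effect of the knockdown on these genes stays open and untested apart from them.

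The second pattern is the fall of 129 genes at or above the median signal. Here 117 kept their call under quantile normalization, and the median change was -0.79 before and -0.77 after, which argues against a trend with brightness as the whole cause. Further probes, 41 in number, covered 34 of the 129 genes. Of these probes 38 also lay lower, with a median of -0.58, some of them near 0, such as a Camk2d probe at -0.02. For the 34 genes as a set this argues against faulty single probes. Genes without a further probe, Akt1 and Mtpn among them, were not checked in this way. Of the 226 such genes called lower without the circHIPK3 siRNA array of the first slide, 224 also lay lower on that array. Its median was -0.72 against -0.70 on the second slide. The siGFP arrays it was set against had also served to choose the genes, so this agreement is not fully independent. All siGFP arrays lie on the first slide, so the second slide has no part in the median of -0.72. It rests on 1 circHIPK3 siRNA array, however, so for single genes slide and knockdown cannot be told apart. An effect of the siRNA on other transcripts was not tested and may equally account for the falls.

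The third pattern is the lower signal of histone genes. With slide as a block, in effect a comparison within the first slide, the list median was -0.33 relative to all genes. It rests on 1 circHIPK3 siRNA array, so the part played by the slide is not decided. A list of 42 DNA replication genes had a median of -0.22 relative to all genes, and -0.14 under quantile normalization, as fewer cells in S phase would give. It lay at percentile 0 of 10000 signal-matched lists, whose own median was -0.09. Those lists were drawn without regard to correlation between members, so the percentile may overstate the difference. Before subtraction of the all-gene median, circHIPK3 siRNA replicate 2 at -0.03 lay within the siGFP range of -0.06 to 0.04. Histone genes with a poly(A) tail (11 measured) had a median of -0.20 at percentile 1.21 (-0.13 under quantile normalization and -0.11 with slide as a block), between the fall of the histone list and no change, and a difference in the capture of RNA without a tail could not be separated from it. Fewer cells in S phase may be a candidate explanation, untested by any measure of cycling, and an effect of the knockdown stays open.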

How the results depend on the processing

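Normexp, cyclic loess, slide as a random block and the first slide alone were chosen after seeing the data. All 30 named genes past the threshold kept their direction under every alternative run. The groups of these 30 genes did not overlap. Leaving out an array, the slide block or the first slide alone therefore could not turn them. The stricter filter, trend and robust variance, and the replicate block leave the change itself as it was. The slide block and the first slide alone gave the same change. The kept directions were thus largely fixed in advance and are weak evidence of robustness. Of 1110 values of named genes under the alternatives, 753 kept direction and side of the threshold, 314 lost the call, 43 gained it and 0 turned. Of 460 gene list values 377 kept both, 38 lost the call, 2 gained it and 43 turned sign. Replicate numbers did not pair the arrays (correlations between -0.13 and 0.27), so the replicate block is given here only. Genes without a well above background signal in a group limit the fold that can be given. The cause of the differences below was not tested.

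The count of 303 genes was 185 in the authors' value table, 605 with median scaling, 0 without a filter on dim probes (5628 at an unadjusted p under 0.05 by limma), 630 with trend and robust variance, 1805 with array weights, 0 with the replicate block (5133), 0 with slide as a fixed block (2675), 125 with slide as a random block and 0 on the first slide alone (2871). Leaving out each array gave 0 to 1736, and 0 stood against 3344 to 5068 genes at an unadjusted p under 0.05 without a siGFP array. Higher and lower genes numbered 38 and 241 with normexp, 48 and 272 with cyclic loess, 203 and 402 with median scaling, 34 and 151 in the value table, 78 and 161 with the stricter filter, 198 and 432 with trend and robust variance, and 1115 and 690 with array weights. The number of lists, 10, was 6 with normexp, 5 with quantile normalization, 5 with cyclic loess, 5 in the value table, 4 with slide as a fixed block, 5 on the first slide alone and 6 to 11 on leaving out each array.

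Hipk3 lay between -0.29 and -0.03 and did not pass under any alternative run. Akt1 was not called without a filter (-0.84), with the replicate block (-0.84) or with slide as a fixed block or the first slide alone (-0.82), and lay between -0.92 and -0.77 on leaving out each array. Mtpn was not called in the same settings (-1.04, -1.04 and -1.23) and lay between -1.10 and -0.94. Slc2a2 passed with normexp (-0.86), median scaling (-1.24), cyclic loess (-1.32), trend and robust variance (-1.14) and array weights (-0.93), and lay between -1.37 and -0.90.

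List medians relative to all genes that turned sign were these. With normexp they were 0.0038 for AKT signalling, 0.0092 for miR-338-3p targets, 0.029 for cholesterol, 0.016 for glycolysis and 0.014 for cytoskeleton. With quantile normalization they were 0.0091 for miR-338-3p targets, 0.039 for cholesterol, 0.036 for glycolysis, -0.053 for delta and PP cells and 0.028 for cytoskeleton. With cyclic loess they were, in that order, 0.012, 0.046, 0.055, -0.053 and 0.025, and 0.0054, 0.041, 0.035, -0.057 and 0.023 in the value table. Without a filter miR-338-3p targets were at 0.0024 and delta and PP cells at -0.0099, with the stricter filter miR-338-3p targets at 0.0034, with array weights glycolysis at 0.032, with the mean of a gene's probes cytoskeleton at 0.0020 and with slide as a random block at 0.013. With slide as a fixed block, and equally on the first slide alone, miR-338-3p targets were at 0.068, interferon at 0.062, p53 targets at 0.014, glycolysis at 0.069 and cytoskeleton at 0.050. Leaving out each array gave -0.046 to 0.039 for miR-338-3p targets, -0.14 to 0.11 for glycolysis and -0.017 to 0.032 for cytoskeleton. Of these lists only cholesterol passed at first, and it was not called where it turned.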

Other observations

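Under the 75th percentile, quantile, median, cyclic loess and normexp settings (5 in all), 157 genes were called each time, 144 lower and 13 higher. Of the falls 116 and of the rises 7 lay at or above the median signal. The genes named here were chosen after their values were seen. The rises at higher signal were Slitrk5, Ap1s2, a clathrin adaptor subunit gene (1.06 ± 0.10, SE), Meig1 (1.07 ± 0.12, SE), Atp6v1a, a subunit gene of the vacuolar proton pump (0.91 ± 0.13, SE), Siae (0.86 ± 0.11, SE), Btg2 and Sspn (0.70 ± 0.09, SE). The falls included the small GTPase genes Rab1b (-1.03 ± 0.13, SE) and Rab10 (-0.93 ± 0.14, SE, with a second probe at -0.17 ± 0.09, SE), the vesicle cargo receptor gene Tmed10 (-0.76 ± 0.10, SE) and the glycosyltransferase genes Dpagt1 (-0.99 ± 0.13, SE) and B4galt3 (-0.73 ± 0.11, SE). With slide as a fixed block, a fit that rests on 1 circHIPK3 siRNA array and does not decide single genes, Slitrk5 lay at 1.31 and Btg2 at 0.75. No enrichment among these genes was tested.

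Called genes with further kept probes were compared probe by probe. Of 49 further probes for genes called lower 44 also lay lower, and of 11 for genes called higher 10 also lay higher. Ap1s2 was an exception, with a second probe at -0.26, and so were Cks1brt (-0.85 and 0.73), Mapk1ip1l (-0.80 and 0.33) and Wdfy4 (-0.57 and 0.53).

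A hypothesis is that loss of circHIPK3 frees miR-124-3p and miR-338-3p, so that their targets fall. The tests, chosen after the results were seen, placed the median of literature targets at percentile 18.1 of signal-matched lists for miR-124-3p and at 73.8 for miR-338-3p. Members went both ways and neither value decides; the single target Mtpn may fall for this or other reasons.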
